A study of Mus musculus with 8 samples.

How the data were processed

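RNA from the duodenum of 8 mice was measured on Clariom S mouse arrays, a 1-colour array with mostly 1 probe set per gene. Per the labels, 4 mice lacked IκBα (gene Nfkbia) in villin-expressing epithelium, and each was compared with a wild-type littermate, which gave 4 sibling pairs. The mice were 8 to 11 weeks old, with 2 males and 2 females in each group by label, and RNA integrity numbers ran from 7.0 to 8.7. The series design names frozen, homogenized duodenum, while the sample labels give small intestine. A step to isolate epithelium is not given in the sources used here, so other cells may contribute RNA.

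The deposited values are log2 expression values per probe set. RMA and Transcriptome Analysis Console 4.0 are named in the submitters' processing notes, and further settings are not given in the sources used here. The medians of the arrays lay between 6.77 and 6.81. The values show a further step that no source used here records: the 4 pair means of a probe set were nearly equal. Their median SD was 0.0175, against 0.0897 expected from the spread of the within-pair differences (median SD 0.179), and in 70.0% of probe sets the 4 pair means lay within 0.05. Deviations of siblings from their group means correlated between −0.913 and −0.870 across probe sets. Most differences between pairs had thus been taken out, so differences between pairs, and SDs within a group, were not interpreted. Some remained: means over pairs 1 and 2 and over pairs 3 and 4 differed by over 0.05 in 13.0% of probe sets, most for Fabp6 (9.84 and 9.00).

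The groups, a first fit, the gene lists, the rule for naming genes and a first set of other settings were chosen before the data were examined. The reported fit departs from that choice. The first fit had genotype alone, which treats the 8 values as independent, although little but 4 within-pair differences remains once most of the pair means are removed. The reported fit has the sibling pair as a block, which was among the other settings. The change rested on the pair means and was made before the calls of the fits were compared, and the counts of the first fit are printed beside the reported ones. The reported fit takes the 4 differences as independent. Across probe sets they correlated more between pairs 1 and 2 (r = 0.682) and between pairs 3 and 4 (r = 0.673) than otherwise (0.346 to 0.420). Its p-values do not allow for this likeness and may be too small. Both fits were tested on simulated data of 22206 probe sets with pair means removed. Unchanged probe sets had p under 0.05 in 5.38% of cases with the block and in 18.1% without it, with 6 and 733 false calls of 22006. With the block, 38% of simulated log2 changes of 0.5 were recovered, as were 70% of changes of 1, 98% of changes of 2 and 100% of changes of 3. Each share rests on 50 probe sets. The simulation changed 200 probe sets in all, fewer than the 1301 called in the data. The adjusted threshold is harder to pass with fewer changes, so these shares do not give the power of the real comparison.

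Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), with Benjamini-Hochberg adjustment over all 22206 probe sets and a threshold of 0.05. All p-values are two-sided unless stated. The number of arrays limits the precision: 3 residual degrees of freedom remained with the block, and 6.63 in all after variance moderation. Values after ± are the SD of the 4 within-pair differences. Of the probe sets, 19572 had 1 gene symbol, 0 had several and 2634 are unnamed here. All 19572 gene IDs were found in the RefSeq table of assembly GRCm38.p6, and 0 symbols needed an update. For 55 genes with more than 1 probe set the one with the highest mean was named, and 0 genes had called probe sets of opposite sign. No detection calls were used. The 95th percentile of 1091 olfactory receptor probe sets, 5.65, served as a background level, and differences of probe sets near it are understated.

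The 41 gene lists comprised 20 of pathways and 21 of cell types, beside 2 reference lists of housekeeping and sex-linked genes. They were tested with camera at its preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, which tests whether the genes of a list move on balance one way. The named genes are the 12 with the largest rise and the 12 with the largest fall among those past the threshold with 1 direction in all 4 pairs, Nfkbia, up to 4 called members of each list (or, with none called, the 2 with the largest change) and 3 sex-linked genes. Predicted gene models were counted and not named. Islet, stomach, adipose and X-linked gene lists were added later, the stomach and adipose ones after some of their genes had been seen to differ.

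The other settings were the fit without the block, a random block, sex or RNA integrity as a covariate, filters on dim probe sets, quantile normalization, centring on housekeeping or epithelial genes, trend and robust variance, array weights, other thresholds, other set tests and leaving out replicates. With the block, leaving out 1 sibling leaves the other without information, so whole pairs were left out. Fits without pairs 3 and 4, without pairs 1 and 2, and with the mean of the acinar or of the adipose genes as a covariate were added after the data had been seen. With the block, either mean mainly sets pairs 1 and 2 apart from pairs 3 and 4. Nfkbia was at −2.24 with the adipose mean and −2.21 without pairs 1 and 2, and at −3.23 with the acinar mean and −3.10 without pairs 3 and 4. These covariates thus cannot tell fat or pancreas from any other difference between those pairs. Single values were tested with exact permutation tests. The comparison by sex used the fit chosen in advance, without the block.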

Results

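The study measured gene expression in the duodenum of 4 mice with a deletion of Nfkbia in the intestinal epithelium (knockout) and of 4 wild-type littermates. Nfkbia encodes IκBα, the inhibitor that holds NF-κB in the cytoplasm and is itself an NF-κB target. Each array gave log2 values for 22206 probe sets. Each knockout was compared with its own sibling, as most differences between sibling pairs had been taken out of the deposited values.

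The deleted gene was examined first, as a check of the labels. Nfkbia was lower in 4 of 4 pairs, with a mean log2 value of 6.96 in knockouts and 9.61 in wild types. The difference of −2.65 ± 0.918 (SD, n = 4 pairs) is 6.29-fold (limma adjusted p = 0.0130). It was −2.93, −3.26, −1.29 and −3.13 in pairs 1 to 4, so pair 3 had the smallest fall. An exact permutation test of 4 against 4 values gave p = 0.0286, the smallest that 70 assignments allow, but it treats siblings as independent. Exact sign flips within pairs gave p = 0.125, the smallest that 16 allow. Without pair 1, 2 or 4 the limma adjusted p was 0.0545, 0.0582 and 0.0512. Over all settings it ran from 2.92e-04 to 0.209. Per the series design the deletion removes the promoter and the first exons in cells with villin-driven Cre, and where the probe set lies on the gene was not analysed here.

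The main comparison asked which genes differ between knockout and wild-type duodenum. Of the genes with the largest changes, Lcn2, which encodes the siderophore-binding protein lipocalin-2, rose by 3.16 ± 0.305 (log2, n = 4 pairs, limma adjusted p = 4.00e-04). The cytokine gene Tnf rose by 2.98 ± 0.385 (adjusted p = 0.00114) and the chemokine gene Ccl20 by 2.61 ± 0.413 (adjusted p = 0.00183). The cytochrome P450 gene Cyp2c55 changed by −4.41 ± 1.22 (adjusted p = 0.00701), the carboxylesterase gene Ces2a by −2.15 ± 0.135 (adjusted p = 4.00e-04) and the lactase gene Lct by −2.84 ± 1.38 (adjusted p = 0.0270).

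In all, 702 probe sets were higher and 599 lower, and each of the 1301 had 1 direction in all 4 pairs. Changes of at least 2-fold were found for 95 higher and 82 lower probe sets. The other genes with the largest rises were Plet1 (3.62 ± 0.944), Ceacam10 (3.0 ± 0.460), the amino acid transporter gene Slc6a14 (2.98 ± 0.682), the acute-phase genes Saa1 (2.69 ± 1.55) and Hp (2.58 ± 1.5) and the complement factor H-related gene Cfhr2 (2.67 ± 0.262). Next came the nitric oxide synthase gene Nos2 (2.55 ± 0.989), the NADPH oxidase gene Nox1 (2.52 ± 0.595) and Duoxa2 (2.47 ± 0.394), whose product matures the oxidase Duox2. Saa1 differed by 4.24, 3.71, 1.85 and 0.94 in pairs 1 to 4 and Hp by 3.73, 4.01, 1.40 and 1.18. Adipose genes, chosen after the data were seen, also differed most in pairs 1 and 2 (medians 4.17 and 3.91, against 0.34 and 0.19 in pairs 3 and 4).

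The other largest falls were those of the olfactory receptor gene Olfr165 (−2.88 ± 1.05), the colipase gene Clps (−2.68 ± 0.562), the ectonucleotidase gene Nt5e (−2.66 ± 0.997), the mast cell protease gene Mcpt1 (−2.47 ± 0.833) and the cytochrome P450 genes Cyp2b10 (−2.46 ± 1.1) and Cyp3a11 (−2.08 ± 0.433). Pnliprp2, a relative of pancreatic lipase (−2.21 ± 0.332), and the serpin gene Serpina1b (−2.15 ± 0.780) fell as well. Cyp2c55, Mcpt1 and Serpina1b averaged 5.31, 4.72 and 5.39 in knockouts, below the background level of 5.65, so their falls are understated. Tnf, Cfhr2, Hp and Nox1 averaged 5.58, 5.02, 5.23 and 5.31 in wild types, so their rises are understated as well. Of the 24 genes with the largest changes, 7 lost their call without pair 1 (adjusted p from 0.0534 to 0.113), 7 without pair 2 (0.0534 to 0.127), 2 without pair 3 (0.0560 to 0.0691) and 4 without pair 4 (0.0504 to 0.0600). Hp lost it in each case, Saa1 without pair 1, 2 or 3, and Olfr165, Nfkbia and Cyp2b10 without pair 1, 2 or 4. Lct lost it without pair 1 or 2, Nt5e without pair 2 and Serpina1b without pair 1. In other settings with the block Saa1 and Hp lost it with sex, both with Nos2 and Cyp2b10 with RNA integrity, and these 4 with Lct and Nt5e with trend and robust variance. Lct and Cyp2b10 lost it with the acinar or adipose mean, Nt5e with the former and Nfkbia with the latter, and Cyp2b10 and Serpina1b with the random block. Without pairs 3 and 4 or without pairs 1 and 2 all 24 lost it.

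**Figure D1:**
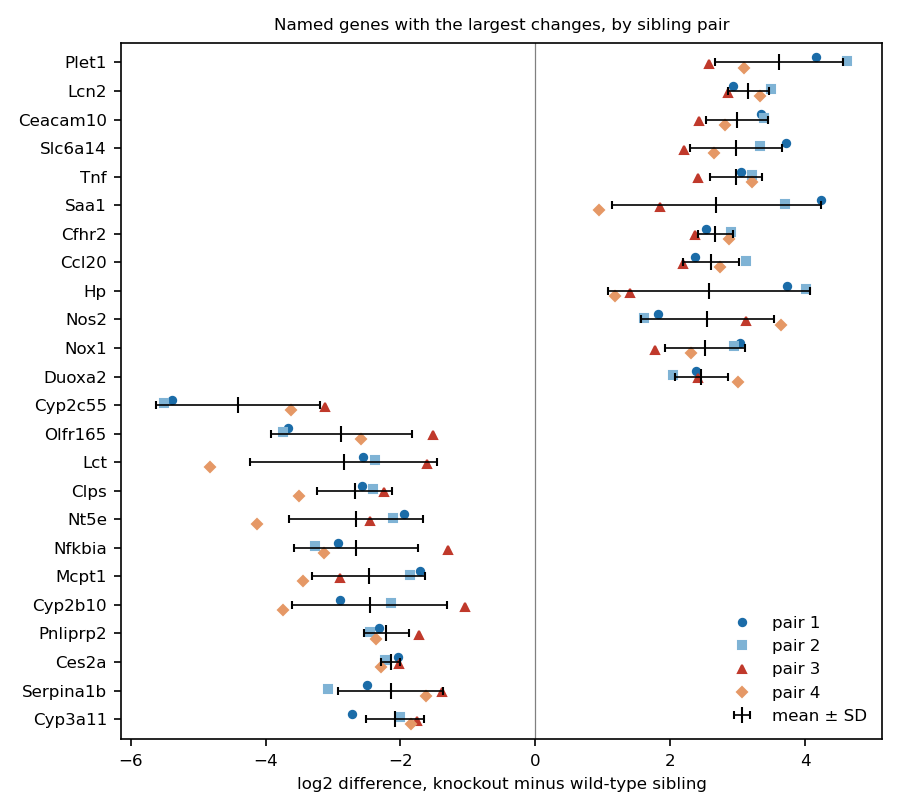
Log2 difference between knockout and wild-type sibling (horizontal axis) for the 12 named genes with the largest rise and the 12 with the largest fall, with coloured symbols for the 4 sibling pairs and black bars for the mean ± SD. No symbol crosses 0, from Plet1 at 3.62 to Cyp2c55 at −4.41.

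Without the block, the fit first chosen, limma called 3622 higher and 4026 lower, and 1300 of the 1301 were among them. The share of higher probe sets among the calls, 54.0%, became 7.96% after centring on housekeeping genes, which moved the median of all probe sets from −0.015 to −0.19, and 33.9% after centring on epithelial genes. The 10 housekeeping genes measured were themselves higher in knockouts, with a median of 0.196 (0.28, 0.205, 0.135 and 0.11 in pairs 1 to 4), and Gusb was called higher. Centring on them lowers every knockout value against its sibling, here and in the lists below. Which scaling is right was not tested. Leaving out pair 1, 2, 3 or 4 left 204, 145, 459 and 239 calls. By limma the fit on pairs 1 and 2 alone made 0 calls (5278 at unadjusted p under 0.05) and that on pairs 3 and 4 alone 26.

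Of the 41 fixed lists, 10 were higher and 7 lower by camera at the preset correlation. With an estimated correlation camera called 0, with 3 at unadjusted p under 0.05, and fry called 3. The other lists called at the preset correlation had fry adjusted p-values from 0.0843 to 0.458. Examples are 0.214 for interferon and B cell, 0.206 for Paneth cell and acinar and 0.168 for proliferation genes. With the estimated correlation camera tests with the 3 residual degrees of freedom, so it could hardly call a list. Its adjusted p-values thus do not decide against a list. Enteroendocrine markers had an estimated correlation of −0.0060, below the preset 0.01, and their camera adjusted p still went from 7.16e-05 to 0.633. Other called lists had estimates far above the preset, such as 0.847 for smooth muscle, 0.835 for Paneth cell, 0.649 for interferon and 0.542 for cholesterol genes. If these estimates hold, the p-values of such lists at the preset correlation are too small. Counts of members over all probe sets are followed below by counts adjusted over the list alone.

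The list of NF-κB feedback and target genes was called higher at the preset correlation: 15 of 40 were higher and 0 lower, and 22 and 2 adjusted over the list alone. The camera adjusted p = 1.69e-07 (median 0.34), the adjusted p = 0.654 with an estimated correlation, and the fry adjusted p = 0.0231. Besides Tnf and Ccl20 the list's calls included the feedback inhibitor Tnfaip3 (1.31 ± 0.128) and the RNase gene Zc3h12a (1.46 ± 0.239). Limma called 6, 6, 10 and 7 of the list higher without pair 1, 2, 3 or 4. Over all probe sets the higher calls fell from 702 to 136, 89, 219 and 143 in the same fits. Lost calls on leaving out a pair are thus not particular to a list, here and below. After centring on housekeeping genes 12 were higher and 6 lower, with a median of 0.16. The list's medians in pairs 1 to 4 were 0.40, 0.39, 0.16 and 0.245. Cell death genes had 5 of 27 higher and 1 lower, and 10 and 1 adjusted over the list alone. The adjusted p = 1.94e-04, the adjusted p = 0.633 with an estimated correlation, and the fry adjusted p = 0.0231. Birc3, which restrains cell death, rose by 0.79 ± 0.0858, and Casp4 (0.91 ± 0.260), the necroptosis effector Mlkl (0.64 ± 0.284) and Casp8 (0.36 ± 0.0926) rose too. Birc3 is also a called member of the NF-κB list, and both lists name Bcl2l1 and Cflar, so these lists are not independent. In the cell death list 2, 1, 3 and 2 were called higher without pair 1, 2, 3 or 4, and 5 higher and 4 lower after centring on housekeeping genes (median 0.02).

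Antimicrobial and acute-phase genes had 6 of 22 higher and 1 lower (11 and 2 adjusted over the list alone, adjusted p = 6.26e-04, adjusted p = 0.714 with an estimated correlation). The lipopolysaccharide-binding protein gene Lbp rose (1.0 ± 0.352), and Reg4 fell (−1.55 ± 0.556). The count of higher members was 3, 2, 2 and 5 without pair 1, 2, 3 or 4, and 9 with 4 lower after centring on housekeeping genes. Without pairs 1 and 2 the list's adjusted p was 0.0640, and with the adipose mean as a covariate 0.0873. Interferon response genes had 6 of 28 higher and 0 lower (12 and 0 adjusted over the list alone, adjusted p = 1.69e-07, adjusted p = 0.714 with an estimated correlation). Oas2 (0.71 ± 0.237), Stat2 (0.47 ± 0.102), Oasl2 (0.65 ± 0.344) and Dhx58 (0.72 ± 0.410) were among them. By limma 0, 0, 1 and 0 of these genes were called without pair 1, 2, 3 or 4 (11, 10, 15 and 18 at unadjusted p under 0.05), and 0 with sex or RNA integrity added to the block. The count was 7 centred on housekeeping genes and 12 with the acinar mean. The list's medians were 0.73 and 0.66 in pairs 1 and 2, the pairs with the adipose difference, and 0.14 and 0.12 in pairs 3 and 4. With the adipose mean as a covariate its adjusted p was 0.0873. That covariate mainly sets pairs 1 and 2 apart, so here and below it cannot tell fat from their other differences. Among 15 MHC class I genes the proteasome activator Psme1 alone was called (0.34 ± 0.0862), with 4 adjusted over the list alone (adjusted p = 0.0442, adjusted p = 0.748 with an estimated correlation). The list's medians were 0.26, 0.31, 0.04 and −0.02 in pairs 1 to 4, larger in the pairs with the adipose difference. Without pair 1 or 2 its adjusted p was 0.203 and 0.191. Without pairs 1 and 2 it was 0.910, and with the adipose mean as a covariate 0.972 with the direction down. On leaving out any 1 pair limma called 0 members (5, 4, 6 and 6 at unadjusted p under 0.05). The list also lost its call with sex, RNA integrity, dim-probe filters, quantile normalization or centring (adjusted p from 0.0511 to 0.252), and centred on housekeeping genes it had 0 higher and 2 lower.

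The cholesterol biosynthesis list was called higher at the preset correlation, with 11 of 18 higher and 0 lower (14 and 1 adjusted over the list alone, median 0.68, adjusted p = 3.58e-09, adjusted p = 0.714 with an estimated correlation, fry adjusted p = 0.0843). They included the sterol-responsive regulator Insig1 (1.23 ± 0.249) and the pathway enzymes Msmo1 (0.70 ± 0.117), Idi1 (0.91 ± 0.230) and Pmvk (0.97 ± 0.317). The count was 4, 2, 5 and 4 without pair 1, 2, 3 or 4, and centred on housekeeping genes 11 were higher and 1 lower. Medians in pairs 1 to 4 were 0.50, 0.40, 0.78 and 0.95, larger in the pairs with the acinar difference. With the acinar mean as a covariate 1 was higher (median 0.42), and the list kept its call. Fat absorption genes had 5 of 21 lower (7 adjusted over the list alone, adjusted p = 6.26e-04, adjusted p = 0.714 with an estimated correlation). The sterol exporters Abcg5 (−0.70 ± 0.181) and Abcg8 (−0.51 ± 0.109), the fatty acid transporter Slc27a4 (−0.66 ± 0.220) and the cholesterol importer Npc1l1 (−0.34 ± 0.0591) were among them. By limma 0, 0, 2 and 0 members were called without pair 1, 2, 3 or 4 (11, 10, 11 and 9 at unadjusted p under 0.05). Without pairs 3 and 4 the list's adjusted p was 0.0845, and with the acinar mean as a covariate 0.336, with 1 higher and 0 lower. It had 12 lower members centred on housekeeping genes. Iron and calcium uptake genes had 2 of 17 higher and 0 lower (7 and 1 adjusted over the list alone, adjusted p = 0.00482, adjusted p = 0.714 with an estimated correlation). Both encode iron transporters, Slc11a2 (1.39 ± 0.442) and Slc40a1 (1.75 ± 0.775), and 1, 2, 1 and 1 were called without pair 1, 2, 3 or 4. Of the list 4 were higher and 2 lower centred on housekeeping genes.

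The proliferation list had 4 of 28 higher, Mki67 (0.51 ± 0.135), Rrm2 (0.51 ± 0.152), Top2a (0.51 ± 0.183) and Prc1 (0.52 ± 0.268). It had 11 adjusted over the list alone (adjusted p = 1.03e-06, adjusted p = 0.714 with an estimated correlation). On leaving out any 1 pair limma called 0 of them (9, 12, 10 and 15 at unadjusted p under 0.05), and 0 with RNA integrity added to the block. After centring on housekeeping genes 3 were higher. The list's medians were 0.37, 0.20, 0.35 and 0.005 in pairs 1 to 4. Among 34 genes of xenobiotic and glutathione metabolism 8 rose and 13 fell (14 and 16 adjusted over the list alone), and the list was not called (median 0.041, mean −0.264, test direction down, adjusted p = 0.705). Ces2a, Cyp3a11 and Cyp3a25 (−1.89 ± 0.476) fell, while the glutathione transferase gene Gsta3 rose (1.88 ± 0.30). The list had 4, 3, 6 and 2 higher and 8, 6, 9 and 5 lower without pair 1, 2, 3 or 4, and centred on housekeeping genes 9 and 16.

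**Figure D2:**
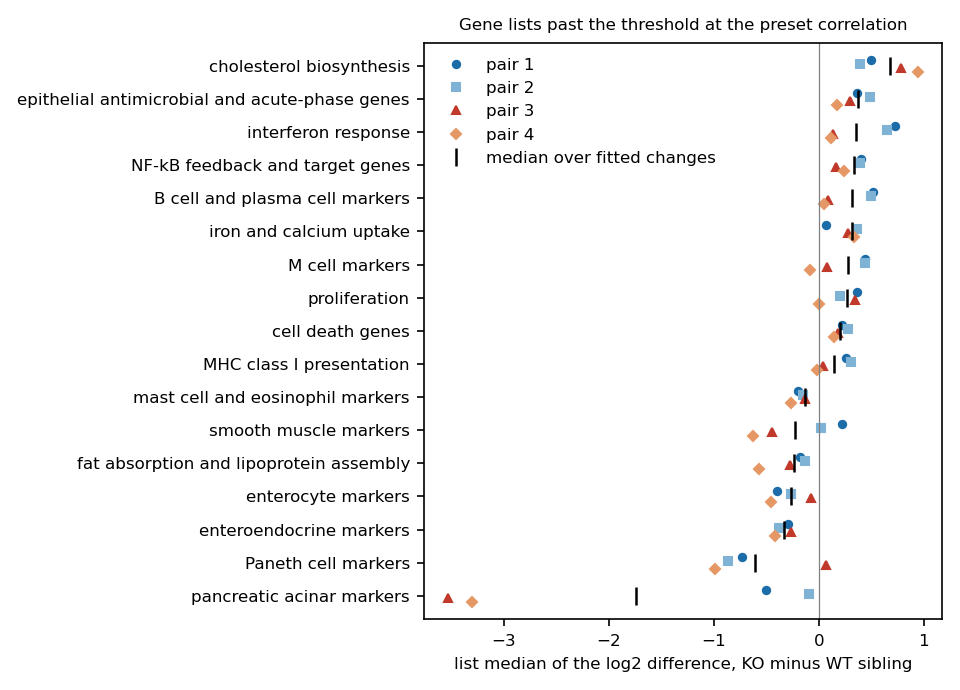
Median log2 difference between knockout and wild-type sibling (horizontal axis) of the 17 lists past the threshold at the preset correlation, with coloured symbols for the 4 sibling pairs and a black mark for the median of the fitted changes. Cholesterol biosynthesis lies highest (0.68) and pancreatic acinar markers lowest (−1.74), the latter with pairs 3 and 4 far below pairs 1 and 2.

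Among epithelial cell types, enteroendocrine markers had 8 of 26 lower and 1 higher, and 13 and 2 adjusted over the list alone. The adjusted p = 7.16e-05, the adjusted p = 0.633 with an estimated correlation, and the fry adjusted p = 0.0247. Cpn1 (−1.14 ± 0.150), the secretin gene Sct (−0.54 ± 0.0574) and Reg4 fell, while the tachykinin gene Tac1 rose (1.56 ± 0.362). The lower members numbered 3, 1, 5 and 2 without pair 1, 2, 3 or 4, 14 centred on housekeeping and 11 on epithelial genes. Paneth cell markers had 3 of 21 lower (19 adjusted over the list alone, median −0.61, adjusted p = 2.32e-07, adjusted p = 0.714 with an estimated correlation). Nupr1 (−0.85 ± 0.338), Habp2 (−1.18 ± 0.60) and the antimicrobial angiogenin Ang4 (−1.84 ± 1.2) fell. The list's medians were −0.73, −0.86, 0.07 and −0.99 in pairs 1 to 4, and pair 3 was also the pair with the smallest fall of Nfkbia. By limma 0, 0, 13 and 0 of its members were called without pair 1, 2, 3 or 4 (10, 11, 20 and 12 at unadjusted p under 0.05). Centring on housekeeping genes gave 19 lower and on epithelial genes 7.

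Enterocyte markers had 5 of 27 lower (10 adjusted over the list alone, adjusted p = 4.48e-04, adjusted p = 0.714 with an estimated correlation). The purine enzyme gene Ada (−0.96 ± 0.371), the trehalase gene Treh (−0.53 ± 0.208) and the amino acid transporter gene Slc6a19 (−0.49 ± 0.191) fell with Lct. Without pair 1, 2, 3 or 4 limma called 0, 1, 3 and 2 of them (12, 11, 14 and 13 at unadjusted p under 0.05), and 15 centred on housekeeping and 8 on epithelial genes. M cell markers had 4 of 16 higher (5 adjusted over the list alone, adjusted p = 0.0141, adjusted p = 0.714 with an estimated correlation). Pglyrp1 (1.65 ± 0.315) and the RANK gene Tnfrsf11a (0.48 ± 0.214) rose with Ccl20 and Tnfaip2 (1.04 ± 0.439), and these last genes are also in the NF-κB list. The M cell list had medians of 0.45 in both pairs with the adipose difference and 0.08 and −0.09 in pairs 3 and 4, and without pair 1 its adjusted p was 0.0735. With the filters on dim probe sets it was 0.0796 and 0.276, without pairs 1 and 2 0.756, and with the adipose mean as a covariate 0.719 (median −0.01). Its higher members numbered 2, 2, 3 and 2 without pair 1, 2, 3 or 4, and 3 with 3 lower after centring on housekeeping genes.

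B cell and plasma cell markers had 3 of 23 higher (3 adjusted over the list alone, adjusted p = 5.39e-06, adjusted p = 0.748 with an estimated correlation). Pou2af1 (0.87 ± 0.247), Tnfrsf13c (0.93 ± 0.409) and Cd22 (0.40 ± 0.103) rose, and the list's medians were 0.52 and 0.50 in pairs 1 and 2 and 0.09 and 0.05 in pairs 3 and 4. By limma 0, 0, 2 and 1 were called without pair 1, 2, 3 or 4 (4, 4, 11 and 12 at unadjusted p under 0.05), and 2 centred on housekeeping genes. Without pairs 1 and 2 its adjusted p was 0.391, and with the adipose mean as a covariate 0.654. Mast cell and eosinophil markers had 4 of 18 lower (6 adjusted over the list alone, adjusted p = 0.0175, adjusted p = 0.714 with an estimated correlation). Mcpt1, Mcpt2 (−1.19 ± 0.615), Kit (−0.78 ± 0.291) and Cpa3 (−1.17 ± 0.659) fell, all known from mast cells. Cpa3 averaged 4.82 in knockouts, below the background level, and 2, 1, 1 and 1 of the list were called without pair 1, 2, 3 or 4 and 7 centred on housekeeping genes. The list's adjusted p was 0.0579 with quantile normalization, 0.147 without pairs 3 and 4 and 0.211 with the acinar mean as a covariate. Among 18 smooth muscle markers only Myocd was called (−0.59 ± 0.194, knockout mean 5.30, below background), with 1 adjusted over the list alone (adjusted p = 0.0442, adjusted p = 0.767 with an estimated correlation, adjusted p = 0.0902 without the block). The list's medians were 0.22, 0.02, −0.45 and −0.63 in pairs 1 to 4, and without pair 3 or 4 its adjusted p was 0.338 and 0.588. On leaving out any 1 pair limma called 0 members (10, 3, 2 and 2 at unadjusted p under 0.05). The list's call was also lost with sex added to the block (0.0525) and centred on epithelial (0.0861) or housekeeping genes (0.124, 8 lower).

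Pancreatic acinar markers were lower as a list (median −1.74, adjusted p = 1.70e-07, adjusted p = 0.714 with an estimated correlation). Of 23, Clps and Try10 (−1.67 ± 0.885) were called, and 12 adjusted over the list alone. Without pair 1, 2, 3 or 4 the calls numbered 1, 2, 1 and 1, and centred on housekeeping genes 16. The medians were −0.50 and −0.09 in pairs 1 and 2 and −3.53 and −3.30 in pairs 3 and 4. Stomach genes, chosen after the data were seen, had medians of −0.52, −0.36, −2.51 and −2.49 in pairs 1 to 4, and 1 of 8 was called, Muc5ac (−0.74, adjusted p = 0.0495). The median hides 2 kinds of gene: Gkn1, Gkn2, Gkn3 and Tff1 differed by −3.81 to −5.41 in pairs 3 and 4, while Atp4a (0.11 and 0.27), Atp4b (−0.47 and −0.13) and Cblif (−0.03 and −0.15), the last below background, hardly differed. Of the 7 adipose genes 0 were called by limma (6 at unadjusted p under 0.05, lowest adjusted p 0.0778). The lower medians of smooth muscle markers lay in the pairs with the acinar difference.

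Covariates added to the block changed the counts of the called lists as well. Each leaves fewer residual degrees of freedom, and sex rests on labels that Y-linked genes, given below, do not bear out. With sex, RNA integrity, the acinar mean and the adipose mean in turn, the higher members numbered 9, 5, 9 and 8 for NF-κB, 2, 2, 4 and 2 for cell death, 3, 4, 8 and 4 for antimicrobial, 5, 4, 1 and 10 for cholesterol and 1, 2, 1 and 3 for iron and calcium genes. In the same order they were 2, 2, 5 and 4 for M cells and 1, 1, 6 and 1 for B cells. By limma they were 2, 0, 1 and 0 for proliferation (15, 14, 11 and 6 at unadjusted p under 0.05), 0, 0, 12 and 1 for interferon (15, 14, 24 and 12) and 0 each time for MHC class I (4, 4, 8 and 4). The lower members numbered 5, 6, 3 and 3 for enteroendocrine, 2, 2, 1 and 5 for mast cell and 1, 1, 2 and 21 for acinar markers. By limma they were 5, 1, 3 and 0 for Paneth cells (19, 19, 17 and 3 at unadjusted p under 0.05), 2, 1, 0 and 1 for enterocytes (15, 15, 10 and 12), 2, 2, 0 and 2 for fat absorption (10, 10, 10 and 14) and 0, 0, 0 and 10 for smooth muscle (2, 4, 3 and 14).

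List medians not given above were, in pairs 1 to 4, 0.22, 0.28, 0.18 and 0.15 for cell death, 0.365, 0.49, 0.295 and 0.175 for antimicrobial and 0.07, 0.36, 0.28 and 0.34 for iron and calcium genes. They were −0.18, −0.13, −0.27 and −0.57 for fat absorption, −0.29, −0.375, −0.26 and −0.415 for enteroendocrine, −0.40, −0.26, −0.07 and −0.45 for enterocyte and −0.20, −0.15, −0.13 and −0.26 for mast cell genes.

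**Figure D3:**
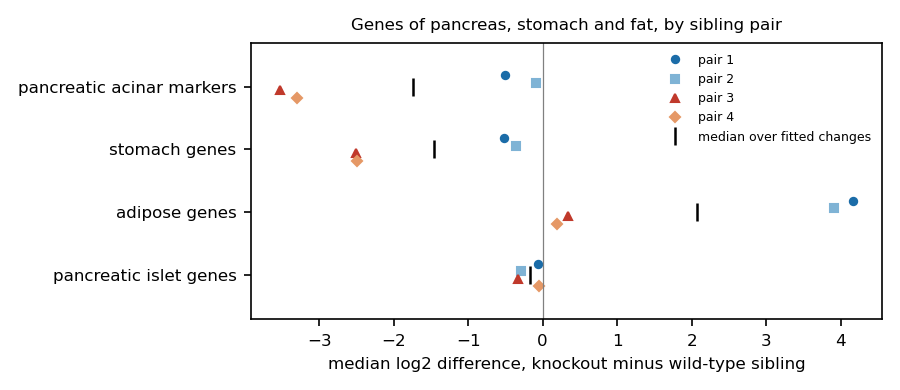
Median log2 difference between knockout and wild-type sibling (horizontal axis) of genes of pancreas, stomach and fat, with coloured symbols for the 4 sibling pairs and a black mark for the median of the fitted changes. Acinar and stomach genes are lower in the knockouts of pairs 3 and 4, adipose genes are higher in those of pairs 1 and 2 (4.17 and 3.91), and islet genes lie near 0.

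The other lists were not called. Of 31 chemokines, Ccl20, Cxcl16 (0.89 ± 0.159) and Ccl28 (0.61 ± 0.230) rose (4 higher and 2 lower adjusted over the list alone, adjusted p = 0.296). The chemokine list was called higher without pair 4 (0.0397), without pairs 3 and 4 (0.0201), with the acinar mean (0.0271) and centred on housekeeping genes (0.0243). MHC class II genes had 0 of 11 called by limma, 0 adjusted over the list alone and 0 at unadjusted p under 0.05 (adjusted p = 0.794), with H2-Eb1 at −0.27 ± 0.408 and H2-Oa at 0.27 ± 0.472. Their medians were 0.21, 0.09, −0.21 and −0.27 in pairs 1 to 4, and the list was called higher without pairs 3 and 4 (0.00754) and lower without pairs 1 and 2 (0.00147). These calls are at the preset correlation, and in the reported fit the adjusted p with an estimated correlation was 0.954 for MHC class II and 0.748 for chemokines. The p53 targets had 0 of 15 called by limma, with 1 higher and 1 lower adjusted over the list alone and 4 at unadjusted p under 0.05 (adjusted p = 0.611). Phlda3 was at 0.58 ± 0.353, with means of 5.05 and 4.48 below background, and Plk2 at −0.33 ± 0.309. Of 30 Wnt genes, Fzd7 (0.86 ± 0.268) and Cd44 (0.52 ± 0.231) rose (2 adjusted over the list alone, median −0.086, mean 0.014, test direction down, adjusted p = 0.705). In the Notch list Mfng rose (0.36 ± 0.109), 1 of 17 and 1 adjusted over the list alone (adjusted p = 0.542). Without pair 1, 2, 3 or 4 limma called 2, 2, 3 and 3 chemokines, 0, 0, 1 and 0 Wnt genes (10, 7, 7 and 9 at unadjusted p under 0.05) and 0 Notch genes each time (1, 2, 1 and 2). Centred on housekeeping genes, higher and lower members numbered 3 and 4 for chemokines, 0 and 2 for MHC class II, 1 and 5 for p53 targets, 2 and 11 for Wnt and 0 and 2 for Notch.

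The unfolded protein response list had Creb3l4 lower (−0.55 ± 0.189), 1 of 23 probe sets and 1 adjusted over the list alone (adjusted p = 0.484). Cldn4 fell in the list of fetal-like epithelium (−0.68 ± 0.359), 1 of 14 and 1 adjusted over the list alone (adjusted p = 0.705). Among 23 genes of fatty acid oxidation Pparg rose (1.02 ± 0.548) and Acaa2 fell (−0.63 ± 0.217), with 2 higher and 6 lower adjusted over the list alone (adjusted p = 0.325). The immediate early gene Btg2 fell (−0.72 ± 0.293), 1 of 22 probe sets and 1 adjusted over the list alone (adjusted p = 0.667). Of 17 clock genes, Nfil3 (0.62 ± 0.179) and Npas2 (0.59 ± 0.192) rose and Cry2 (−0.50 ± 0.103) and Nr1d1 (−0.98 ± 0.603) fell. Adjusted over the list alone 5 were higher and 4 lower (median −0.105, test direction up, adjusted p = 0.927). Clock genes had 0 calls by limma without pair 1, 2 or 4 (6, 7 and 10 at unadjusted p under 0.05) and 2 higher and 2 lower without pair 3. On leaving out a pair Creb3l4 was called without pair 3 alone, as the 1 member of its list (9, 5, 5 and 7 at unadjusted p under 0.05), and fetal-like (4, 4, 3 and 4) and immediate early genes (4, 4, 4 and 5) had 0. Fatty acid oxidation then had 0, 0, 1 and 0 higher and 0, 1, 1 and 0 lower (10, 9, 8 and 8). Fetal-like medians were 0.26, 0.05, −0.24 and −0.24 in pairs 1 to 4, and that list was called lower without pairs 1 and 2 (0.00975, against 0.896 in the reported fit with an estimated correlation). Centred on housekeeping genes, higher and lower members numbered 0 and 5 for the unfolded protein response, 0 and 4 for fetal-like, 1 and 9 for fatty acid oxidation, 0 and 7 for immediate early and 2 and 5 for clock genes. With the adipose mean fatty acid oxidation had 0 and 4.

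Of 26 goblet cell markers, Clca3b rose (0.99 ± 0.0842) and Scin (−1.20 ± 0.400), Tpsg1 (−0.39 ± 0.0709) and Gfi1 (−0.43 ± 0.137) fell. Adjusted over the list alone 2 were higher and 4 lower (median 0.056, mean −0.024, test direction up, adjusted p = 0.776). Stem cell markers had Clca3b and Prom1 (0.91 ± 0.437) higher of 21, 2 adjusted over the list alone (adjusted p = 0.296). Tuft cell markers had 0 of 23 called by limma, 0 adjusted over the list alone and 4 at unadjusted p under 0.05 (adjusted p = 0.667), with Avil at −0.45 ± 0.299 and Trpm5 at −0.36 ± 0.451. Of 13 Brunner gland markers Dmbt1 rose (0.92 ± 0.167) and Galnt6 fell (−0.50 ± 0.132), and Pgc was called at −0.61 ± 0.197 with means of 4.56 and 5.16, both below background (2 higher and 4 lower adjusted over the list alone, adjusted p = 0.258, and 0.0475 without pair 2). On leaving out pair 1, 2, 3 or 4 goblet cell markers had 0, 0, 1 and 1 lower (9, 8, 7 and 7 at unadjusted p under 0.05), stem cell markers 1 higher each time, and Brunner gland markers 0 lower each time (6, 7, 6 and 6). The Brunner gland list was also called lower without pairs 1 and 2 (0.00975, against 0.748 in the reported fit with an estimated correlation). It holds Gkn1, also counted among the stomach genes, which differed by −4.89 and −4.67 in pairs 3 and 4. Centring on housekeeping genes gave 1 higher and 5 lower goblet, 2 and 3 stem cell, 0 and 5 tuft and 1 and 6 Brunner gland markers.

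Of 17 proximal markers Slc40a1 rose and 5 fell, Ada, Lct and the ketohexokinase gene Khk (−0.44 ± 0.0493) among them. Adjusted over the list alone 5 were higher and 6 lower (median 0.185, camera direction up, fry direction down, adjusted p = 0.995). The 5 lower became 1 on leaving out any pair, the higher ones 1, 2, 0 and 0 without pair 1, 2, 3 or 4 (13, 13, 11 and 11 at unadjusted p under 0.05). Centred on housekeeping genes the proximal list was called higher (0.0481, against 0.998 in the reported fit with an estimated correlation), with 5 higher and 6 lower members. Fabp6 rose among 16 distal markers (0.41 ± 0.0529), with 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.267). It was the 1 call not made without the block, where its adjusted p was 0.294. Elf3 (0.54 ± 0.111) and Cdx1 (0.44 ± 0.128) rose in the epithelial content list of 19 (5 higher and 2 lower adjusted over the list alone, adjusted p = 0.484). The latter had 0, 0, 1 and 0 calls by limma without pair 1, 2, 3 or 4 (7, 8, 6 and 5 at unadjusted p under 0.05), and distal markers had 0 higher and 0, 0, 1 and 1 lower (6, 5, 7 and 6). Centring on housekeeping genes gave 0 higher and 7 lower distal and 1 and 7 epithelial markers.

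Cd4 rose (0.40 ± 0.134) among 27 T cell markers, with 2 higher and 2 lower adjusted over the list alone. The list pointed down (adjusted p = 0.0711) and passed the threshold without pair 1, 2 or 3 (adjusted p 0.0102, 0.0475 and 0.0449). It also passed with sex (0.0233) or RNA integrity (0.0108) added to the block, with the filters on dim probe sets (0.0138 and 0.0487) and with quantile normalization (0.0426). The same held without pairs 1 and 2 (0.00819) and with the adipose mean as a covariate (0.00121). It was not called without pair 4 or without pairs 3 and 4. All of these are at the preset correlation, and in the reported fit the adjusted p with an estimated correlation was 0.748. Clec9a (0.62 ± 0.290) and Flt3 (0.39 ± 0.132), known from dendritic cells, were called among 25 macrophage and dendritic cell markers, but the means of both lay below background in both groups (4.80 and 4.18 for Clec9a, 5.47 and 5.08 for Flt3). Adjusted over the list alone 3 were higher and 1 lower (median 0, mean 0.055, adjusted p = 0.484, and 0.0393 without pair 4). The list was also called higher without pairs 3 and 4 (0.00190) and with the acinar mean (0.00197), against 0.896 in the reported fit with an estimated correlation, and its medians were 0.34, 0.15, −0.04 and −0.29 in pairs 1 to 4. Lcn2 was the only call among 19 neutrophil markers (1 higher and 2 lower adjusted over the list alone, median −0.025, mean 0.118, test direction up, adjusted p = 0.894). Of 23 fibroblast markers Timp1 rose (0.77 ± 0.324, wild-type mean 5.29, below background) and Fbln1 fell (−1.01 ± 0.414), with 1 and 1 adjusted over the list alone (median 0.005, mean −0.059, test direction down, adjusted p = 0.894). The endothelial gene Eng rose (0.64 ± 0.0954), 1 of 18 and 1 adjusted over the list alone (adjusted p = 0.0792, and 0.00622 without pair 4). The endothelial list was called as well without pairs 3 and 4 (0.00983), with the acinar mean (0.0191) and centred on housekeeping genes (0.0475), against 0.748 in the reported fit with an estimated correlation. Enteric neuron and glia markers had 0 of 17 called by limma, 0 adjusted over the list alone and 4 at unadjusted p under 0.05 (adjusted p = 0.471), with Vip at −0.50 ± 0.401 and Ret at 0.33 ± 0.173.

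For these lists too the counts moved with the pairs and the scaling. Limma called 0 T cell markers without pair 1, 2, 3 or 4 (11, 9, 10 and 5 at unadjusted p under 0.05) and 0, 0, 1 and 0 of both the macrophage (4, 6, 8 and 6) and the endothelial list (3, 2, 2 and 5). In the fibroblast list the higher call stayed without pair 3 alone and the lower one without pair 3 or 4 (4, 3, 2 and 5 at unadjusted p under 0.05). Fibroblast medians were 0.22, 0.19, −0.16 and −0.29 in pairs 1 to 4, and that list was called higher without pairs 3 and 4 (0.00190) and lower without pairs 1 and 2 (0.00400), against 0.982 in the reported fit with an estimated correlation. Centred on housekeeping genes, higher and lower members numbered 0 and 13 for T cells, 2 and 4 for macrophages, 1 and 5 for neutrophils, 1 and 6 for fibroblasts, 1 and 2 for endothelium and 0 and 6 for neurons and glia.

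The labels give 2 males and 2 females per genotype, and the last comparison asked whether the genotype difference depended on sex. With limma 0 probe sets were called for the interaction (140 at unadjusted p under 0.05), and 0 with the pair as a block (248 at unadjusted p under 0.05). The former is 0.630% of probe sets, far under the share a working test gives by chance, and the block left 1 residual degree of freedom. The 0 calls thus say little. The Y-linked genes Eif2s3y, Kdm5d and Uty did not follow the labels. In pair 3, labelled as a male knockout and a female wild type, they differed by −0.07, 0.00 and −0.24. In pair 4, labelled the other way, the differences were −0.02, −0.04 and −0.25, so the interaction rests on sex labels that these genes do not bear out. Kdm5d lay at 5.34 to 5.38 in pairs 3 and 4, below the background level, so its differences say little. A gap between pairs remained in these genes, with Eif2s3y, Kdm5d and Uty at 7.33, 5.85 and 6.30 over pairs 1 and 2 and at 6.85, 5.37 and 5.90 over pairs 3 and 4.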

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

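The test on islet genes was chosen before its result was seen, and those on the other acinar, stomach, adipose, Clps, Y-linked, X-linked, crypt and position values after.

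In 3 of 116 named genes and 4 of 41 lists, 1 sibling pair stood apart from the other pairs by its gap to the nearest. Of all probe sets 4.11% did so, and chance marks about 1 in 20. Nfkbia differed by −1.29 in pair 3, against −2.93, −3.26 and −3.13 in the others. Cyp3a25 differed by −2.60 in pair 4 and Avil by −0.90 in pair 1. Among list medians, immediate early genes stood apart in pair 1 (0.055), stem cell markers in pair 3 (0.16), proximal markers in pair 2 (0.93) and neutrophil markers in pair 3 (0.12).

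Acinar genes were lower in the knockouts of pairs 3 and 4: the 22 other than Clps had a median of −0.22 over pairs 1 and 2, which argues against 1 effect of like size shared by the 4 pairs. A smaller shared fall stays open, as 11 acinar genes were lower in all 4 pairs and the list median was −0.50 in pair 1. Adipose genes at 0.20 over pairs 3 and 4 argue against fat on the same wild-type samples. Clps and Pnliprp2 were at −2.38 or lower over pairs 1 and 2, where the lowest other acinar gene, Try10, was at −0.94, which argues against pancreas carried over in pairs 3 and 4 as their whole cause. For the other acinar genes such tissue may account for the difference and stays open: islet genes averaged −0.147 over pairs 3 and 4 and −0.156 over pairs 1 and 2, which met the bound set against it in advance by less than their spread (SD 0.249). Of the 6 genes 4 lie below background, and the other 2, Ins2 and Ucn3, were at 0.115 and −0.02 over pairs 3 and 4, which counts against such tissue without deciding. Tissue from the stomach side stays open too, with stomach genes at −2.51 over pairs 3 and 4, since that list was written after some of its genes had been seen. Gkn1, Gkn2, Gkn3 and Tff1 differed there by −3.81 to −5.41, while Atp4a and Atp4b, both above background, hardly differed. The list does not separate parts of the stomach, so the latter genes do not decide. A first test gave −0.21, but it pooled the list with the adipose genes and cannot decide either.

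Y-linked genes were alike within pairs 3 and 4, although the labels give 1 male and 1 female in each. Sex removed gene by gene along with the pair means is argued against by a ratio of 1 between the median size of the difference of pairs 3 and 4, which carries the labelled sex, and that of pairs 1 and 2. Sex labels of pairs 3 and 4 that do not match the samples remain a candidate explanation, as 4 X-linked genes that escape inactivation had a median difference of 0.02 between pairs 3 and 4 (range −0.31 to 0.14), where the labelled sexes would put it below 0. No biological explanation was tested.

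Paneth cell markers were lower in pairs 1, 2 and 4 and not in pair 3. Less crypt base in the knockout samples would lower the stem cell and proliferation lists by about as much. Stem cell medians of 0.03 in each of those pairs lay at least 0.76 above the Paneth medians. In pairs 1 and 2 this is beyond the SD of their members (0.350 and 0.382), which counts against less crypt base without deciding. In pair 4 it barely is (SD 0.999). The stem cell list holds Gkn3, also counted among the stomach genes, which at −4.01 in pair 4 widens that SD. Proliferation medians of 0.365, 0.20 and 0.005 lay above the Paneth medians by more than their SD too. That list was itself called higher in knockouts, so it cannot gauge the crypt base sampled. The bound on the SD was set after these values were seen. The stem cell list had an estimated correlation of 0.035, against 0.835 for the Paneth list. Whether the stem cell list follows the crypt base sampled is thus not shown. Another position along the intestine stays open, as proximal minus distal medians were −0.07, 1.23 and −0.02 but members of the proximal list went both ways. An effect of the deletion, which the design names, was not tested apart from these.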

How the results depend on the processing

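The fits without pairs 3 and 4 or pairs 1 and 2, and those with the acinar or adipose mean, were chosen after the data were seen. All 1301 calls kept their sign in every setting that tested them, which leaving out pairs could not change, since each had 1 direction in all 4. Counts of higher and lower probe sets (702 and 599 with the replicate block) were 3622 and 4026 with no replicate block, and 3368 and 3742 with sex added to that. With the block they were 231 and 233 with sex, 212 and 152 with RNA integrity, 376 and 234 with the acinar mean, 0 and 0 without pairs 3 and 4 (limma, 5278 at unadjusted p under 0.05) and 1 and 25 without pairs 1 and 2. The adipose mean gave 400 higher, trend and robust variance 1135 higher, and the random block 982 lower. Centring gave 5735 lower on housekeeping genes, which were themselves higher in knockouts (median 0.196), and 1158 lower on epithelial genes. An adjusted p under 0.1 gave 1673 and 1631, unadjusted p under 0.05 with 2-fold change 117 and 134, and adjusted p under 0.05 with 1.5-fold change 304 and 240. Leaving out 1 pair gave 89 to 219 higher and 56 to 240 lower. Fewer pairs leave fewer degrees of freedom, and so does a covariate added to the block, which by itself lowers the counts. Sex as a covariate also rests on labels that the Y-linked genes of pairs 3 and 4 do not bear out. For the other settings the cause was not tested.

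Nfkbia kept its direction in every setting and lost its call without pairs 3 and 4 (−3.10, adjusted p = 0.0696), without pairs 1 and 2 (−2.21, adjusted p = 0.209) and with the adipose mean (−2.24, adjusted p = 0.0616). Leaving out 1 pair gave −3.11 to −2.45, and the call was also lost without pair 1, 2 or 4 (limma adjusted p = 0.0545, 0.0582 and 0.0512). The adjusted p of Nfkbia over all settings ran from 2.92e-04 to 0.209. The 17 called lists became 0 with an estimated correlation (3 at unadjusted p under 0.05), where camera has 3 degrees of freedom. They became 3 with fry, and 15 to 19 in the other settings. MHC class II (adjusted p = 0.00754 and 0.00481), fibroblast (0.00190 and 0.00493) and smooth muscle lists (0.0679 and 0.0626) turned higher without pairs 3 and 4 and with the acinar mean. Without pairs 1 and 2 and with the adipose mean, MHC class II (0.00147 and 3.74e-04), fibroblast (0.00400 and 4.79e-04), fetal-like (0.00975 and 0.00171) and Brunner gland lists (0.00975 and 0.0117) were called lower, all at the preset correlation. The acinar list turned with its own mean as covariate (0.944), by construction, and MHC class I with the adipose mean (0.972), and for the others the cause was not tested. The replicate block changed 1 list call, that of smooth muscle, and without it Fabp6 lost and 5 named genes, Phlda3, Plk2, Avil, Vip and Ret, gained a call. Of 115 named genes besides Nfkbia, 45 to 75 kept their side of the threshold without 1 pair and 0 reversed. The interaction with sex had 0 calls in every limma setting (140 at unadjusted p under 0.05, 248 with the block). Camera was not run with the random block. Changes of probe sets near 5.65 are understated.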

Other observations

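The search of gene families and the look at adipose and stomach genes were chosen after the data were seen, and the tests of the genes near Nfkbia and of other splits before.

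Among 656 gene families with at least 5 measured members, 2 held more calls than other genes in 1 direction (one-sided Fisher's exact tests, adjusted over 1312 tests). The Cyp3a family of drug-metabolizing cytochromes P450 had 7 of 9 members lower and 0 higher (adjusted p = 5.37e-07), with medians of −1.35, −1.0, −1.38 and −1.34 in pairs 1 to 4. The family median stayed below 0 under each scaling, at −1.34 with quantile normalization, −1.52 centred on housekeeping genes and −1.40 centred on epithelial genes. Its members share much sequence, so their probe sets are not independent. The Btbd35f family had 6 of 22 lower (adjusted p = 0.0146), but its median level of 4.14 lies below the background level, 1 of the 22 lay above it, and 0 to 2 were called by limma on leaving out a pair. The aquaporin genes (4 of 11 lower) and the Hsd17b genes (4 of 11 lower, 1 higher) each missed the threshold (adjusted p = 0.0537).

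The adipose gene Adipoq differed by 5.10 and 4.84 in pairs 1 and 2 and by 0.85 and 0.21 in pairs 3 and 4, and the stomach gene Gkn2 by −1.27 and −1.14 in pairs 1 and 2 and by −5.16 and −5.41 in pairs 3 and 4. The within-pair differences of all probe sets correlated more between pairs 1 and 2 (r = 0.682) and between pairs 3 and 4 (r = 0.673) than across (0.346 to 0.420). These are correlations across genes, which are not independent replicates. The p-values of the reported fit take the pairs as independent and do not allow for this likeness.

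Of the 8 ways to swap siblings between the groups, 1, the real one, gave as many as 1301 calls with the block, and the highest other gave 0. The swaps are too few for a share under 0.05. Without the block, 1 of 35 splits gave as many as 7648, and the highest other, 265, set knockouts 1 and 2 and wild types 3 and 4 against the rest. Only 8 of the 35 part all 4 pairs. The other splits, 24 that part 2 pairs and 3 that part 0, gave 0 calls with limma, and for those 3 the removal of pair means fixes this. The comparable splits are again too few.

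Strain variants carried along with the targeted allele would put more calls near Nfkbia. Of its 80 nearest measured genes, 4 were called (5.0%, exact binomial 95% interval 1.38% to 12.3%), Psma6, Stxbp6, Scin and Togaram1, against 5.95% of other genes (one-sided Fisher's exact p = 0.708). The share met the bound set against this in advance, but its interval includes an excess, so such variants stay open.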
